A study of Homo sapiens with 4 samples.

How the data were processed

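The 4 libraries come from HEK293 lines with a stably integrated, doxycycline-inducible empty vector, MSI1, SRRM3 or SRRM4, with groups taken from the labels. Each library has a file without a header that gives an Ensembl gene ID, a deposited cRPKM value with 2 decimals (a corrected RPKM, read density per gene length and library size) and a deposited whole-number read count. The genome build is GRCh38 (hg38) per the submitters' processing notes. The aligner, the counting program, its annotation release and whether it used strand are not given in the sources used here. The deposited RPKM values were checked against the deposited counts: over 3759 well-covered genes the ratio of count to cRPKM between libraries equalled the ratio of total counts within rounding, so cRPKM is the count divided by the library total and a gene-specific length. The files list 41614 genes, of which 1426 have no value in any library and were left out. Symbols were found for 39633 of the remaining 40188, and coordinates and gene types come from GENCODE 29 on GRCh38.

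The main measure was log2 of the ratio of cRPKM values after adding a pseudocount of 0.5 to each, which understates differences of low genes. Genes with a mean cRPKM of at least 1 over the 4 libraries were tested, 12706 in all and 11612 of them protein-coding. A gene counted as higher or lower at an absolute log2 fold of at least 1, leaving out the induced gene of the comparison. With 1 library per group this is a rule of size and not a test. Exact conditional (Clopper-Pearson) 95% intervals of the count ratio were computed for each gene. Reads are not independent molecules, so the intervals cover counting error only. A count of 3 or fewer sets the floor, about 0.05 CPM in each library.

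Gene lists (26, of which 3 were primary) were fixed before the data were examined. For each list with at least 5 members passing the filter, the median log2 fold was placed among 10000 random lists matched on mean expression in 20 bins, and was said to stand apart outside the central 95% of these lists. The genes named in the text follow a rule also fixed in advance. It takes the induced genes with MSI2, SRRM1 and SRRM2, then up to 10 genes per direction and comparison from the 2-fold count whose interval excludes 1, ranked by the interval bound nearest to no change and leaving out symbols with a set of prefixes of clone-based and non-messenger genes. The set did not cover all such genes, so an RNVU1 and some antisense genes are named. It adds up to 8 shared genes per direction and up to 4 members per list and comparison with the largest absolute fold. The 27 shared genes are listed in full and REST was added because of its list.

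The procedure was tested on simulated counts with 200 genes changed. For SRRM3 against the empty vector, with 12706 genes, 61.0% of genes changed 2.5-fold and 88.0% of genes changed 4-fold were recovered; the pseudocount keeps low genes under the 2-fold rule. In the same simulation 15 unchanged genes passed the fold rule, 1 of them with an interval excluding 1, and the intervals covered the true ratio for 95.47% of genes. Counting noise for the gene counts and for the overlap was simulated 20 times, with levels scaled in the same way.

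Alternatives fixed in advance were pseudocounts of 0.1 and 2, no filter on low values, a mean cRPKM of at least 5, centring on the median fold, CPM with TMM factors from edgeR, a 1.5-fold rule and the 2-fold rule with the interval. For lists they were the mean in place of the median and another library as control, and for the overlap disjoint controls. Counts of protein-coding genes only, and random lists drawn from protein-coding genes, were chosen after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.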

Results

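The series measured polyA-selected, stranded RNA-seq in HEK293 cells, a human embryonic kidney line. Stable lines carried a doxycycline-inducible transgene and were induced for 24 h at 1 µg/mL. There were 4 groups with 1 library each: an empty vector, MSI1 (an RNA-binding protein), SRRM3 and SRRM4 (serine/arginine-rich proteins that promote inclusion of neural microexons). The series title names the regulation of retinal microexons by these proteins. The values used here are gene-level, so they show transcript abundance and cannot show exon inclusion. Total counts were 62083851 for the empty vector, 63003121 for MSI1, 62892722 for SRRM3 and 60288244 for SRRM4. With 1 library per group no difference below has a replicate check, no p-value was computed across genes, and a difference between lines cannot be separated from an effect of the transgene. Intervals are 95% counting intervals of the ratio of a pair of libraries; they cover counting error only and compare libraries, not conditions. Folds are ratios of depth-scaled counts unless log2 is stated.

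Each transgene was highest in the library labelled for it. MSI1 (ENSG00000135097, GRCh38 chromosome 12, 120341330 to 120369180) was at 62.43 cRPKM in its own library, 7.45-fold the empty vector (7.06 to 7.87), against 8.38 in the empty vector, 10.56 in SRRM3 and 8.19 in SRRM4. SRRM3 (ENSG00000177679, chromosome 7, 76201900 to 76287288) was at 38.53 cRPKM in its own library and 0.49 in the empty vector, a ratio of 78.2 (64.7 to 95.3). SRRM4 (ENSG00000139767, chromosome 12, 118981495 to 119163051) was at 63.78 cRPKM in its own library and 0.39 in the empty vector, a ratio of 165 (144 to 191). SRRM1 and SRRM2, which share the family name, lay between 41.65 and 47.84 cRPKM and between 87.39 and 94.61 cRPKM over the 4 libraries. MSI2, the paralog of MSI1, was at 21.78 cRPKM in the empty vector and 17.54 in MSI1, a ratio of 0.805 (0.780 to 0.831).

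**Figure D1:**
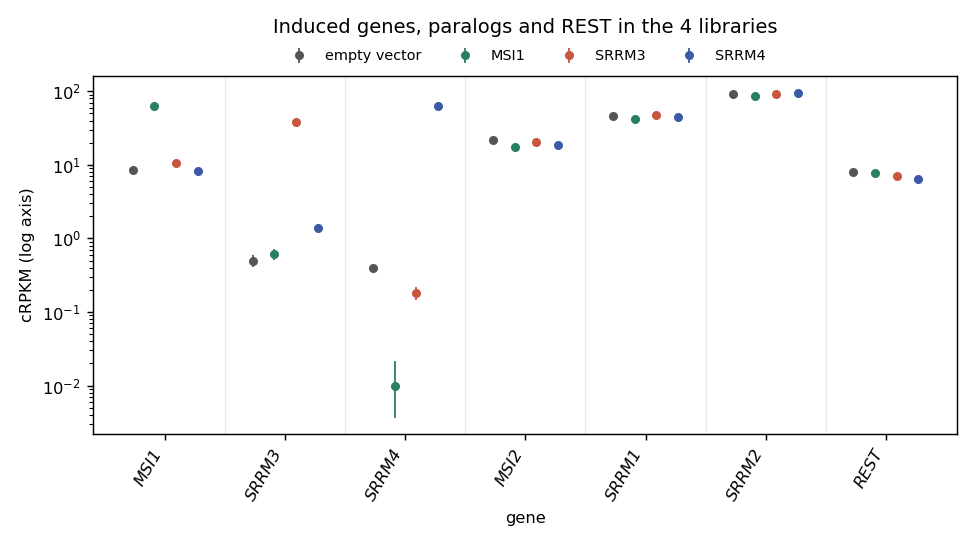
Level of each gene (x axis) in cRPKM on a log axis (y axis), 1 point per library with its 95% counting interval. MSI1, SRRM3 and SRRM4 are each highest in their own library, at 62.43, 38.53 and 63.78 cRPKM.

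MSI1 against the empty vector asks which transcripts differ when MSI1 is induced. Interferon response genes were among the lower genes. IFIT1 (chromosome 10, 89392546 to 89406486), an antiviral RNA-binding protein, was at 1.51 cRPKM against 12.54, a ratio of 0.121 (0.102 to 0.142). IFIT2, IFIT3, IFITM1 and IFI6 had ratios of 0.123, 0.202, 0.133 and 0.358. The interferon list had a median log2 fold of -0.41, below all 10000 matched random lists, with 13 of 16 members lower and 4 of them at least 2-fold lower with an interval excluding 1. IFIT genes are similar to each other in sequence, so the split of reads among them is uncertain. The REST list had a median of 0.20 at percentile 99.95 with no member 2-fold higher, and this call was lost with a pseudocount of 2 (median 0.088), with either other filter (0.042 and 0.12) and for the mean (0.17). Other genes lower in MSI1 were PCDH19 (a protocadherin, ratio 0.273), GDF15 (a stress-induced cytokine, 0.226), DNASE1L2 (0.353), IGFBP5 (an IGF-binding protein, 0.427) and LGR5 (a Wnt-pathway receptor, 0.452).

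Genes higher in MSI1 included RHOB (a small GTPase; chromosome 2, 20447074 to 20449445) at 102.73 against 34.54 cRPKM, a ratio of 2.97 (2.88 to 3.07). PTPRN, a dense-core vesicle protein, had a ratio of 9.05 (6.31 to 13.4) from 0.14 cRPKM. CNN1 (calponin), IGF2, CPA4, SLC6A17, CRABP2 (a retinoic acid carrier), KLF2, ANKRD1 and PLPP2 had ratios of 4.30, 3.65, 3.63, 3.16, 2.80, 3.02, 2.63 and 2.80. In total 38 genes were at least 2-fold higher and 47 at least 2-fold lower among 12705 tested. Of these 27 and 18 also had an interval excluding 1. By the 2-fold rule without the interval, counting noise alone gave means of 8.05 and 8.2 genes in simulation. The simulated levels were scaled too low, so that the pseudocount acted as 2, and these means understate noise for the main rule. They are to be set against the observed counts with a pseudocount of 2, which were 10 higher and 23 lower. The 10 higher genes lay within the simulated range of 4 to 13. Among protein-coding genes alone the counts were 21 higher and 15 lower.

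SRRM3 against the empty vector asks which transcripts differ when SRRM3 is induced. CPLX2 (complexin 2, a regulator of synaptic vesicle fusion; chromosome 5, 175796310 to 175884020) was at 9.54 against 0.11 cRPKM, a ratio of 89.3 (63.4 to 130). SYT4 (synaptotagmin 4) had a ratio of 52.1, XKR7 35.9, ACTL6B (a subunit of the neuronal BAF complex) 32.1, PHF21B 31.3, CHRNB2 (a nicotinic receptor subunit) 29.9, CHGA (chromogranin A) 27.4, UNC13A 25.9, PTPRN 16.9 and PCSK1 (a prohormone convertase) 14.0. Of 26 members of the list of genes repressed by REST, a silencer of neuronal genes outside neurons, 24 were higher and 17 were at least 2-fold higher with an interval excluding 1. The median log2 fold of that list was 1.53, above all 10000 random lists. The filter uses the mean over all 4 libraries, so some members passed only through their levels in SRRM3 and SRRM4. SYT4, for example, was at 0.06, 0.03, 3.31 and 1.68 cRPKM in the empty vector, MSI1, SRRM3 and SRRM4. This raises the median and the share of raised members, here and for SRRM4 over the empty vector. The list also stood apart without the filter. SRRM4 is itself a member of this list. The synaptic vesicle list had a median of 0.27 at percentile 99.99, with 4 of 21 members at least 2-fold higher; with a mean cRPKM of at least 5 required, its median was 0.035 and within the random lists.

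The lower genes in SRRM3 were led by CCN2 (connective tissue growth factor; chromosome 6, 131948176 to 131951373) at 3.31 against 16.94 cRPKM, a ratio of 0.196 (0.177 to 0.216). ANKRD1, ACTBL2, TMEM47, MGST1, IL32, TAGLN (transgelin) and TNFRSF12A had ratios of 0.219, 0.272, 0.369, 0.335, 0.335, 0.389 and 0.476. CCN2 was also lower in MSI1 than in the empty vector, at 9.27 cRPKM. ACTBL2 shares sequence with other actins, and the antisense genes ZNF433-AS1 (0.329) and TM4SF18-AS1 (0.285) are uncertain because strand use in the counting is not given in the sources used here. In total 74 genes were at least 2-fold higher and 38 lower among 12705, of which 55 and 11 had an interval excluding 1. By the 2-fold rule without the interval, counting noise alone gave means of 9.3 and 9.45 genes in simulation. As for MSI1, these understate noise for the main rule. They are to be set against the observed counts with a pseudocount of 2, which were 32 higher and 18 lower. Higher genes made up 66.1% of the 2-fold calls, and 79.5% (58 higher, 15 lower) with CPM and TMM factors in place of cRPKM, which also drops the scaling by gene length.

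SRRM4 against the empty vector asks the same of SRRM4. CPLX2 had a ratio of 51.2 (36.3 to 74.7), XKR7 34.1, SYT4 26.5, UNC13A 24.3, PHF21B 19.7, CHRNB2 19.1, ACTL6B 17.6, CHGA 12.8, SCG3 (secretogranin 3) 11.7 and CHGB (chromogranin B) 8.84. In the REST list 25 of 26 members were higher and 14 were at least 2-fold higher with an interval excluding 1, with a median log2 fold of 1.26 above all random lists; SRRM3, with 2.82-fold the count of the empty vector, is a member. The synaptic vesicle list had a median of 0.098 at percentile 99.5, with 4 of 21 members at least 2-fold higher; without the filter on low values, with the stricter one or with MSI1 as control it lay within the random lists. The interferon list had a median of -0.30, below all random lists, with 16 of 16 members lower and 3 at least 2-fold lower; over MSI1, where these genes were also low, it lay within the random lists (0.069). Only 4 genes met the rule for naming on the lower side: IFIT1, IFIT3, IFIT2 and IFITM1, with ratios of 0.259, 0.30, 0.319 and 0.409. In total 70 genes were at least 2-fold higher and 28 lower among 12705, of which 46 and 7 had an interval excluding 1. By the 2-fold rule without the interval, counting noise alone gave means of 8.55 and 9.65 genes in simulation. As for MSI1, these understate noise for the main rule. They are to be set against the observed counts with a pseudocount of 2, which were 31 higher and 12 lower. The 12 lower genes lay within the simulated range of 5 to 14. Higher genes made up 71.4% of the 2-fold calls, and 94.2% (49 higher, 3 lower) with CPM and TMM factors in place of cRPKM.

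Taking the 4 libraries together, 31 genes were at least 2-fold higher in both SRRM3 and SRRM4 than in both the empty vector and MSI1, and 27 of them had intervals excluding 1 in all 4 pairings. They were CPLX2, PHF21B, SCG3, CHGB, CHGA, UNC13A, ACTL6B, CHRNB2, MMP24, XKR7, SYT4, SYP, PCSK1, RUNDC3A, CELSR3, CPLX1, MPP3, DRD2, AP3B2, SYN1, NMNAT2, TMEM145, TMEM198, ASPHD1, CCDC92B, NAPB and VGF. Of the 27, 12 were on the REST list, against 0.053 by the list's share of the tested genes, and 14 were on neither the REST nor the synaptic list. Some genes passed the filter only through their levels in SRRM3 and SRRM4, so that share is not matched on baseline level. CHGA, for example, was at 0.76, 1.39, 20.81 and 9.70 cRPKM in the empty vector, MSI1, SRRM3 and SRRM4. In the lower direction 5 genes met the fold in all pairings: the small RNA genes MIR2110, MIR6516, MT-TK, RNU6-1075P and SNORD5, named after their values were seen, each with at most 5 reads in a library and none with intervals excluding 1. Of the other ways to pair the libraries, MSI1 with SRRM4 gave 0 higher and 9 lower genes, of which IFIT1, IFIT3 and IFITM1 had intervals excluding 1. MSI1 with SRRM3 gave 0 higher and 4 lower genes, with 0 having such intervals.

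**Figure D2:**
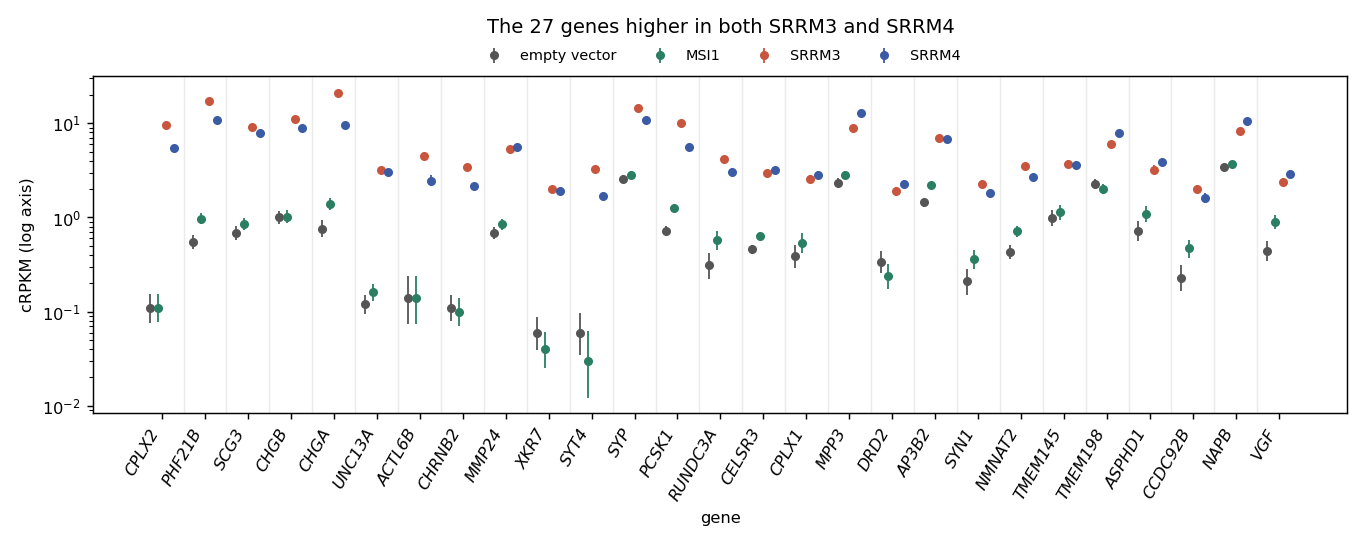
Level of the 27 genes (x axis) in cRPKM on a log axis (y axis), 1 point per library with its 95% counting interval. The SRRM3 and SRRM4 points lie above the empty vector and MSI1 points for each gene, as the rule that chose them requires.

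The SRRM3 and SRRM4 comparisons shared 51 of their 74 and 70 higher genes and 11 of their 38 and 28 lower genes. Both use the same empty-vector library. Simulated unchanged libraries gave means of 2.85 and 3.25 shared genes, from much smaller lists of 8.5 and 8.35 higher and 9 and 9.35 lower genes. The simulated levels were scaled too low, so that the pseudocount acted as 2. With that pseudocount the observed comparisons shared 21 higher and 5 lower genes. Independent lists of the observed sizes would share 0.408 and 0.084. The covariance of the log2 folds over 12703 genes was 0.040 against 0.0045 in simulation, which holds counting noise only. The same scaling shrinks the simulated covariance, so these values are not like for like. The correlation was 0.563 against 0.488 in simulation, so unchanged libraries with a shared control correlate nearly as much. With disjoint controls (SRRM3 over the empty vector, SRRM4 over MSI1) 34 higher and 5 lower genes were shared. The covariance was then 0.013 and the correlation 0.165. Part of the excess with the shared control may therefore come from that library. MSI1, which is not an SRRM protein, shared 10 higher and 10 lower genes with SRRM3, and 13 higher and 18 lower with SRRM4. Its covariances, also with the shared control, were 0.027 with SRRM3 and 0.029 with SRRM4.

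SRRM4 against SRRM3 compares the related proteins directly, without the empty vector. CCN2 was at 30.52 cRPKM in SRRM4 and 3.31 in SRRM3, a ratio of 9.22 (8.38 to 10.2). ANKRD1 had a ratio of 5.80, ACTBL2 3.59, TAGLN 3.52, TNFRSF12A 2.97, IL32 2.87, EGR1 (an immediate early transcription factor) 2.81, CCN1 2.76 and PKP3 2.36. The small nuclear RNA gene RNVU1-30, one of a multicopy family, had no reads in SRRM3. The immediate early list, which holds CCN1, CCN2 and EGR1, had a median of 0.39 above all random lists, with 3 of 23 members at least 2-fold higher. Lower in SRRM4 were IFIT1 (0.264), IFITM1 (0.227), IFI6 (0.379), ISG15 (0.377) and IFIT3 (0.360), along with PLPPR3 (0.328), MGAT3 (0.362), CRMP1 (0.393), SFRP5 (0.381) and IGFBP5 (0.463). The interferon list had a median of -0.46, with 16 of 16 members lower. The REST list was slightly lower in SRRM4, with a median of -0.21 at percentile 0.03, 19 of 25 members lower and CHGA more than 2-fold lower. In total 35 genes were at least 2-fold higher and 30 lower among 12704, of which 14 and 14 had an interval excluding 1.

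**Figure D3:**
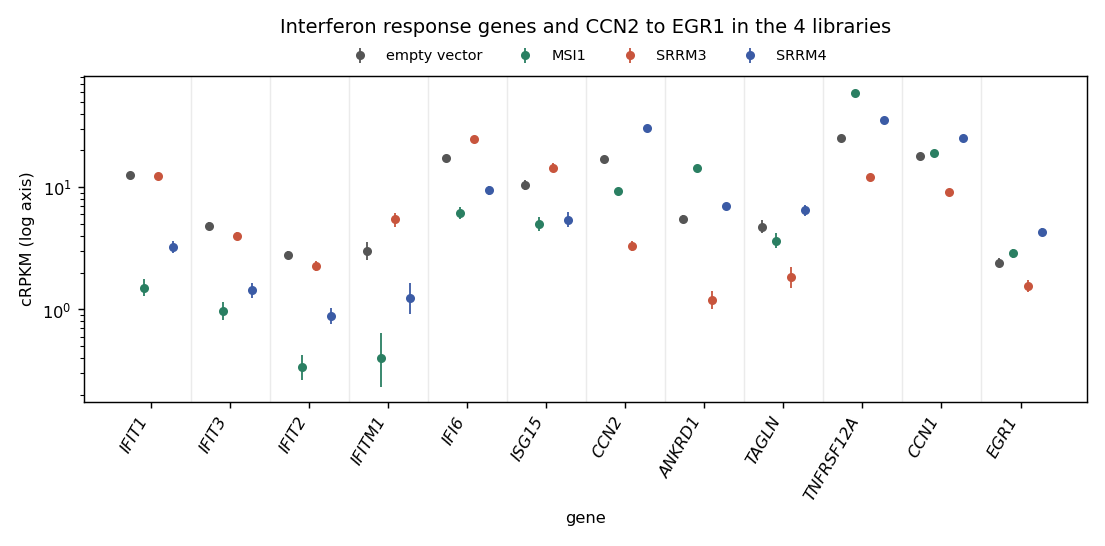
Level of 12 genes (x axis) in cRPKM on a log axis (y axis), 1 point per library with its 95% counting interval. IFIT1 is at 12.54 and 12.3 cRPKM in the empty vector and SRRM3 and at 1.51 and 3.25 in MSI1 and SRRM4, and CCN2 is lowest in SRRM3 at 3.31.

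The genes that host the neural microexons did not stand apart at the gene level. The median log2 fold of 55 microexon host genes was 0.011 in MSI1, 0.018 in SRRM3 and -0.0034 in SRRM4 over the empty vector, and no member was 2-fold different. The largest values were 0.48 for KIF1A in MSI1, 0.43 for SNAP91 in SRRM3 and -0.37 for CLASP2 in SRRM4. Host genes of photoreceptor exons (13 members) were within the random lists, with medians of -0.020, -0.093 and -0.017. Of 36 photoreceptor genes only UNC119 and GNB3 passed the filter, so that list was not tested; the 34 others reached at most 0.75 cRPKM. The fibroblast and blood cell lists had 4 and 3 members passing and were not tested either.

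SR and SR-like splicing proteins (40 members) had medians of -0.076 in MSI1 (percentile 1.07), 0.035 in SRRM3 (95.98) and 0.054 in SRRM4 (98.79); with MSI1 as control the SRRM3 median was 0.088 and stood apart. RBM39 was at 81.76 cRPKM in the empty vector and 108.45 in SRRM4. The hnRNP and tissue splicing regulators had a median of -0.080 in MSI1 (percentile 0.55) and were within the random lists in SRRM3 and SRRM4. That call was lost for the mean (-0.071), and with MSI1 as control the list stood apart in SRRM3 (0.096) and SRRM4 (0.097). Cilium genes were slightly lower in SRRM3 (median -0.082) and SRRM4 (-0.10), with DYNC2H1 at 5.61 cRPKM in the empty vector and 4.17 in SRRM4. The Notch list had a median of 0.12 in SRRM3, with 17 of 23 members higher, while MYC on the same list had a log2 fold of -0.61; this call was lost for the mean.

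The ATF4 list had a median of 0.19 in MSI1, with CHAC1 and SLC7A11 at log2 0.94 and 0.69, while its only 2-fold member, GDF15, was lower. It had medians of -0.080 and -0.061 in SRRM3 and SRRM4. The nonsense-mediated decay list had a median of 0.17 in MSI1, which includes ATF4 itself. Heat shock genes had medians of 0.15 in MSI1 and -0.20 in SRRM3. HSPA1A and HSPA1B are near-identical, so the split of reads between them is uncertain. The unfolded protein response list was at -0.12 in SRRM3. The p53 target list was at -0.084 in MSI1 and -0.21 in SRRM4, with 23 of 25 members lower in the latter. Cholesterol synthesis genes were at 0.071 in SRRM3 and -0.12 in SRRM4, and INSIG1 was at 48.82 and 29.58 cRPKM. Epithelial markers (7 members) were at 0.35 in MSI1 and 0.29 in SRRM3. As lists of RNA quality, the histone genes (6 members) had medians of -0.23, -0.22 and -0.34, and the 13 mitochondrially encoded mRNAs had medians of 0.28, 0.61 and 0.090. With another control the mitochondrial call in MSI1 was lost (-0.066), and that in SRRM4 turned to lower (-0.15 over MSI1). The lists for cytosolic ribosomal proteins, hypoxia and glycolysis, G1/S and DNA replication, and G2/M were within the random lists in each comparison with the empty vector, with medians between -0.080 and 0.049, although the last 3 stood apart under some alternatives. The calls of the histone list were lost without the filter on low values, for the mean and with another control. Those of the epithelial list were lost without the filter and with another control, and those of the unfolded protein response list in SRRM3 and the p53 list in MSI1 for the mean and with another control. With MSI1 as control the calls of the cilium list and of the cholesterol list in SRRM3 were lost, and the decay list stood apart in SRRM3 (-0.29) and SRRM4 (-0.11). In each of the 4 comparisons 11 of 23 lists stood apart where chance would give about 5%. Genes of a pathway vary together between any 2 cultures, which random lists of unrelated genes do not capture, so a list standing apart describes these libraries only.

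**Figure D4:**
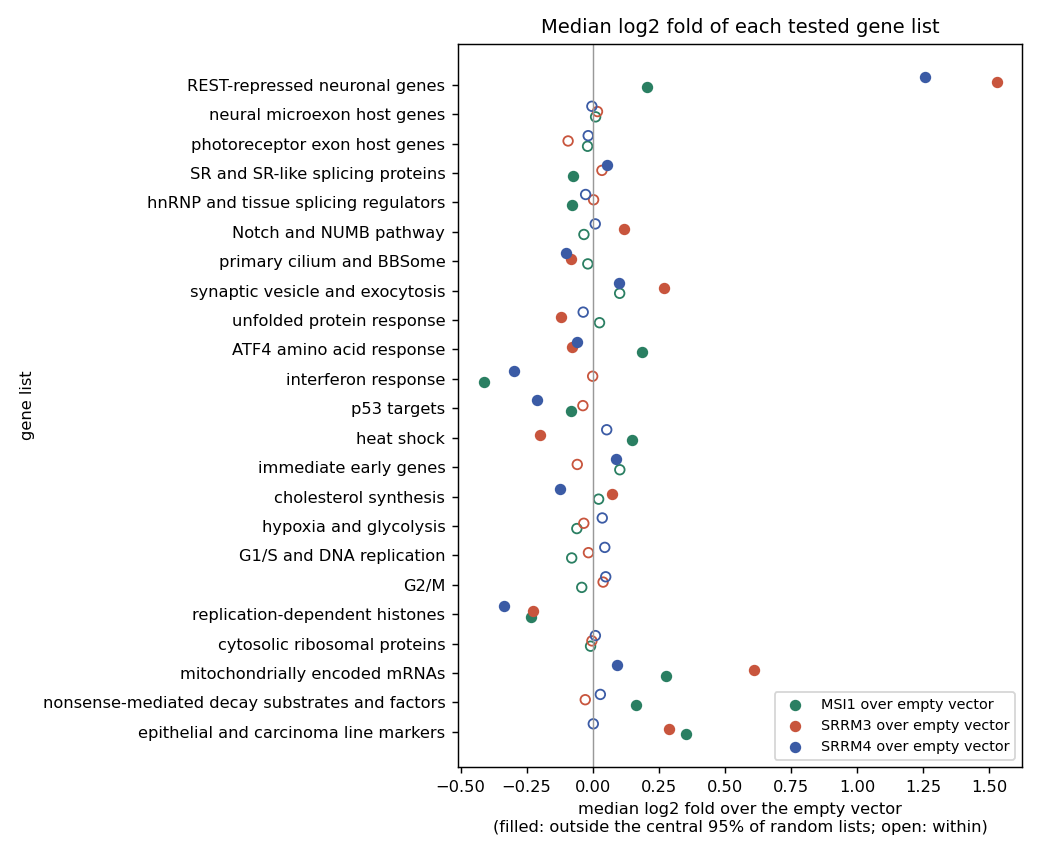
Median log2 fold over the empty vector (x axis) of each of the 23 tested gene lists (y axis), 1 point per comparison. Filled points lie outside the central 95% of matched random lists and open points within it. The REST list in SRRM3 and SRRM4, at 1.53 and 1.26, lies farthest from 0.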

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

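The tests of a deviating empty-vector library below were chosen after the values they use had been seen, while those of a shared batch and of YAP-TEAD activity were written before their results. Among the genes named in SRRM4 against SRRM3, which differ at least 2-fold between these libraries, 11 had SRRM3 and SRRM4 on opposite sides of the empty vector, each by more than counting error. The difference between SRRM3 and SRRM4 was not tested, since each group has 1 library. On the log2 scale SRRM4 exceeded SRRM3 by 3.025 for CCN2 (-2.195 and 0.831 over the empty vector), 2.138 for ANKRD1, 1.573 for TAGLN, 1.531 for TNFRSF12A, 1.417 for CCN1 and 1.239 for EGR1. In the other direction the log2 fold of SRRM4 over SRRM3 was -1.774 for IFITM1, -1.355 for IFI6, -1.33 for ISG15, -1.126 for SFRP5 and -1.085 for IGFBP5.

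The flagged genes CCN2, ANKRD1, TAGLN, TNFRSF12A, CCN1 and EGR1 were lowest in the SRRM3 library. They were picked for their difference between SRRM3 and SRRM4. The immediate early list, which holds CCN1, CCN2 and EGR1, was within the random lists in SRRM3 over the empty vector (percentile 5.585), but stood apart as lower without the filter on low values (-0.083), with the stricter filter (-0.11), for the mean (-0.27) and with MSI1 as control (-0.36). A deviation of the empty-vector library stays open: the median log2 fold of these genes in SRRM3 over MSI1 was -1.181 (SD 0.954, 6 of 6 lower), but they were chosen for a low level in SRRM3, which largely fixes that outcome. Lower YAP-TEAD activity was weighed because CCN1, CCN2 and ANKRD1 are targets of that pathway. The other 13 signature genes passing the filter had a median at percentile 53.9 (log2 0.025, SD 0.22, 8 higher and 5 lower), which argues against a broad fall of the signature, though members going both ways leave a fall of a few targets open. Differences in density or handling between the cultures, and a property of this line, were not tested.

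Interferon response genes were low in MSI1 and SRRM4. A batch shared by these libraries that moves many genes at least 2-fold is argued against. By that rule, with intervals excluding 1, only 1 gene outside the interferon list (IFITM1, itself interferon-induced) separated them from the other libraries. By the same rule 27 genes separated SRRM3 and SRRM4. Smaller shifts could not register in this count, so a batch of smaller shifts stays open. A deviation of the empty-vector library alone needs SRRM3 to be as low as MSI1 and SRRM4, which it was not. The pattern was named with these values in view, so the medians below restate it and are no independent test. The list's median over SRRM3 was -0.59 in MSI1 (SD 0.839, 14 of 16 members lower) and -0.462 in SRRM4 (SD 0.542, 16 of 16 lower), both below all 10000 random lists. A first bound, a gap of over 0.3 between the medians over the empty vector of SRRM3 and of the higher of the other libraries, was not met at 0.297 and was replaced after its value was seen, since an SRRM3 library equal to the empty vector could not have met it. A deviation shared by the empty vector and SRRM3 stays open. No effect of MSI1 or SRRM4 on these genes can be separated from a difference between the lines.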

How the results depend on the processing

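Counts of protein-coding genes only and random lists drawn from protein-coding genes were not planned and were chosen after seeing the data. With 1 library per group no library could be left out, and depth limits the low genes. Gene counts depended on the settings: 30 of 100 values under alternatives were within 1.5 times the main count. Centring on the median log2 fold kept all 12 counts within that range. The cause of the other differences was not tested, except that stricter filters test fewer genes and larger pseudocounts shrink the folds of low genes. With a pseudocount of 0.1 the counts were 60 higher in MSI1. With a pseudocount of 2 the counts were 10 higher and 23 lower in MSI1, 32 higher and 18 lower in SRRM3, 31 higher and 12 lower in SRRM4, 16 higher and 12 lower in SRRM4 over SRRM3 and 15 higher and 2 lower shared by SRRM3 and SRRM4. With no filter on low values the counts were 125 higher and 118 lower in MSI1, 171 higher and 106 lower in SRRM3, 153 higher and 85 lower in SRRM4, 112 higher and 103 lower in SRRM4 over SRRM3 and 47 higher and 13 lower shared by SRRM3 and SRRM4. With a mean cRPKM of at least 5 the counts were 6 higher and 13 lower in MSI1, 15 higher and 7 lower in SRRM3, 13 higher and 2 lower in SRRM4, 7 higher and 7 lower in SRRM4 over SRRM3 and 6 higher and 0 lower shared by SRRM3 and SRRM4. With CPM and TMM factors (0.990 to 1.015) in place of cRPKM, which changes 2 choices at once, the counts were 22 higher and 28 lower in MSI1, 15 lower in SRRM3, 3 lower in SRRM4, 12 higher and 13 lower in SRRM4 over SRRM3 and 0 lower shared by SRRM3 and SRRM4. With the 1.5-fold rule the counts were 218 higher and 147 lower in MSI1, 219 higher and 112 lower in SRRM3, 152 higher and 81 lower in SRRM4, 112 higher and 166 lower in SRRM4 over SRRM3 and 48 higher and 13 lower shared by SRRM3 and SRRM4. With the interval required the counts were 18 lower in MSI1, 11 lower in SRRM3, 46 higher and 7 lower in SRRM4, 14 higher and 14 lower in SRRM4 over SRRM3 and 0 lower shared by SRRM3 and SRRM4. With protein-coding genes only the counts were 21 higher and 15 lower in MSI1, 49 higher and 10 lower in SRRM3, 40 higher and 5 lower in SRRM4, 11 higher and 14 lower in SRRM4 over SRRM3 and 0 lower shared by SRRM3 and SRRM4. The overlap of SRRM3 and SRRM4 was 12 higher and 0 lower with a mean cRPKM of at least 5, 21 higher and 5 lower with a pseudocount of 2, and 5 lower with either pair of disjoint controls.

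Of 613 list values under alternatives 546 kept their call. The REST list in SRRM3 and SRRM4 and the interferon list in MSI1 and in SRRM4 over SRRM3 kept theirs under all that were run. The other control below is MSI1 for SRRM3 and SRRM4, and the mean of SRRM3 and SRRM4 for MSI1, so that the REST list in MSI1 takes the other side by construction. Values are the median (or mean) log2 fold, over the empty vector unless stated, and the cause of each change was not tested. With a pseudocount of 2 the REST (0.088 in MSI1) list no longer stood apart. With a pseudocount of 2 the immediate early (0.091 in MSI1) and G1/S (-0.079 in MSI1) lists came to stand apart. With no filter on low values the REST (0.042 in MSI1), synaptic (0.044 in SRRM4), histone (-0.045 in MSI1, -0.045 in SRRM3, -0.0091 in SRRM4) and epithelial (0.029 in MSI1, 0.056 in SRRM3, -0.040 in SRRM4 over SRRM3) lists no longer stood apart. With no filter on low values the immediate early (0.11 in MSI1, -0.083 in SRRM3) and G1/S (-0.080 in MSI1) lists came to stand apart. With a mean cRPKM of at least 5 the REST (0.12 in MSI1) and synaptic (0.035 in SRRM3, -0.037 in SRRM4) lists no longer stood apart. With a mean cRPKM of at least 5 the Notch (-0.098 in MSI1), heat shock (0.059 in SRRM4) and immediate early (-0.11 in SRRM3) lists came to stand apart. With the mean in place of the median the REST (0.17 in MSI1), hnRNP (-0.071 in MSI1), Notch (0.11 in SRRM3, -0.11 in SRRM4 over SRRM3), unfolded protein (-0.077 in SRRM3) and p53 (-0.043 in MSI1) lists no longer stood apart. With the mean in place of the median the hypoxia (0.078 in SRRM4 over SRRM3) and histone (-0.20 in MSI1, -0.18 in SRRM3, -0.23 in SRRM4) lists no longer stood apart. With the mean in place of the median the heat shock (0.091 in SRRM4), immediate early (0.15 in MSI1, -0.27 in SRRM3), hypoxia (-0.076 in SRRM3) and decay (-0.084 in SRRM3) lists came to stand apart. With the other control the cilium (-0.056 in SRRM3, -0.088 in SRRM4), synaptic (0.046 in SRRM4), unfolded protein (-0.082 in SRRM3), interferon (0.069 in SRRM4) and p53 (0.055 in MSI1) lists no longer stood apart. With the other control the cholesterol (0.051 in SRRM3), histone (0.063 in MSI1, 0.0001 in SRRM3, -0.029 in SRRM4), mitochondrial (-0.066 in MSI1) and epithelial (0.062 in MSI1, -0.061 in SRRM3) lists no longer stood apart. With the other control the SR protein (0.088 in SRRM3), hnRNP (0.096 in SRRM3, 0.097 in SRRM4), Notch (-0.17 in MSI1, 0.094 in SRRM4), interferon (0.59 in SRRM3) and heat shock (-0.083 in SRRM4) lists came to stand apart. With the other control the immediate early (-0.36 in SRRM3), hypoxia (-0.083 in MSI1, 0.11 in SRRM4), G1/S (-0.11 in MSI1, 0.074 in SRRM3), G2/M (0.074 in SRRM3, 0.10 in SRRM4) and decay (-0.29 in SRRM3, -0.11 in SRRM4) lists came to stand apart. With the other control the epithelial (-0.28 in SRRM4) list came to stand apart. With the other control the REST (-1.16 in MSI1) and mitochondrial (-0.15 in SRRM4) lists stood apart on the other side. Of 1776 values of named genes under alternatives 1497 stayed within the counting interval, 279 moved and 0 changed sign.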

Other observations

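Low reads of the induced genes outside their own libraries differed between lines. SRRM4 had 201 reads in the empty vector, 95 in SRRM3 and 6 in MSI1. SRRM3 was at 1.39 cRPKM in the SRRM4 library, 2.82-fold the empty vector (2.25 to 3.54). The 17 REST list members below the filter had median levels of 0.02, 0.04, 0.29 and 0.13 cRPKM in the empty vector, MSI1, SRRM3 and SRRM4. PTPRN was higher than in the empty vector in all 3 other libraries, at 1.29, 2.41 and 1.05 cRPKM against 0.14. The share of counts from mitochondrial genes was 0.88% in the empty vector, 1.07% in MSI1, 1.33% in SRRM3 and 0.94% in SRRM4, and MT-CO2 was at 2860.05 cRPKM in SRRM3 against 1700.08 in the empty vector.

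The higher level of the REST-repressed list in SRRM3 and SRRM4 was weighed against several explanations; the tests of the empty vector and of REST mRNA were chosen after the values were seen, the other tests before. A deviating empty-vector library is argued against by the medians over MSI1, of which the smaller was 1.091. Neuronal cells or RNA are argued against because the median gain of abundant neuronal transcripts was 0.04 cRPKM in SRRM3 and -0.113 in SRRM4. This was at most 0.013 of the median gain of the raised members. Those members were chosen for their rise, which favours a small ratio. NEFL and NEFM have a high baseline in these cells that would hide a small share. NEFM itself was higher in SRRM3, at 19.44 cRPKM against 11.32 in the empty vector and 15.73 in MSI1, but not in SRRM4 (11.84). Over the 6 markers with a baseline under 1 cRPKM, chosen after the values were seen, the median gain was -0.005 in SRRM3 and 0.005 in SRRM4. Of these, SNAP25 (0.08 cRPKM in the empty vector, 0.96 in SRRM3 and 1.35 in SRRM4) and STMN2 (0.01, 0.29 and 0.07) were higher, DCX had 0 reads in all 4 libraries, and GAP43, SYT1 and MEG3 were not higher than in the empty vector. SNAP25, STMN2 and GAP43 are themselves on the REST list, so they are not independent of the pattern. The planned test of reads of the induced genes assigned to other genes cannot decide. By the way the list was tested, 0 of the 17 raised members could be SRRM genes. An equal share of such reads in both libraries is argued against by a comparison chosen after the values were seen. SRRM4 had 32240 reads in its library and SRRM3 8634 in its own. The list was still lower in SRRM4 than in SRRM3 (median log2 fold -0.21, 19 of 25 members lower). An unequal share stays open. A lower level of REST mRNA stays open: REST was at 0.899 and 0.819 of the empty vector in SRRM3 and SRRM4, lower by more than counting error (smaller lower bound 0.779), and how large a loss the list would need was not measured. A first bound of 0.67 on the lower bound would have argued against it and was replaced after the values were seen, since it had no such basis. REST is also on the list of neural microexon host genes. Its exon inclusion cannot be seen in gene-level values and was not tested.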
